A study of Mus musculus with 24 samples.

How the data were processed

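RNA from mouse kidney and testis was measured on Illumina Mouse-6 bead arrays, with 12 arrays per tissue and 24 in all. Per the labels, total RNA was extracted with RNeasy columns and DNase treatment and labelled with biotin. The groups were unirradiated controls and 3 dose rates, with 3 arrays per group in each tissue. For arrays, their number limits the precision of every value given here.

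The kidney table was made in Illumina BeadStudio 1.5.0.34 with rank-invariant normalization, per the file headers. Its signal is an intensity on a linear scale, which the authors had already normalized and background-subtracted before it was deposited. A detection score per probe and array, deposited in the same table, is a fraction from 0 to 1 in which values near 1 mark probes brighter than the negative controls. The number of beads averaged per probe was also deposited and was used only to describe the arrays. The other 23 per-sample columns of that table, which hold bead spreads and difference scores, were not used here. Testis signals come from the deposited value table of the series, where they are an intensity on a linear scale with values below 0. How the authors normalized the testis arrays is not given in the sources used here. Kidney signals in that value table did not differ from the kidney table, with a largest difference of 0. The kidney table held 46116 probes after 4 control entries were left out, and the value table held 46133 probes, of which 17 had no kidney value.

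Target identifiers in the kidney table, rather than gene symbols, name the probes. A zero-padded number inside the identifier was read as an NCBI gene ID and looked up in the mouse reference table (GRCm38.p6). Of 11897 such numbers, 82.6% were gene IDs of that table, against 11.3% of 16535 unpadded numbers of 5 digits. This named 9832 probes with 8127 symbols, of which 1500 had more than 1 probe, and left 36284 probes without a symbol. The naming was checked in 455 pairs of probes with the same symbol, whose kidney minus testis differences had r = 0.74, while the highest value over 1000 random pairings was 0.158. Of 20 nephron marker probes, 16 were higher in kidney (median log2 difference +4.52), and all 14 germ cell marker probes were lower (median log2 difference −8.67). None (0) of 10000 random namings gave as large a gap.

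Analyses ran in R 4.3.3 with limma 3.58.1. Kidney signals were background-corrected, quantile normalized and put on a log2 scale with limma neqc, using the detection scores and an offset of 16. A probe was kept if its score was above 0.99 on at least 3 arrays, which left 10903 probes. The noise SD that neqc estimated was 175 to 218 intensity units per array. When it was estimated from scores between 0.05 and 0.95 alone it was 20.9 to 29.5, so the log2 differences of dim kidney probes are pulled towards 0 in the values given here. Testis signals under 16 were set to 16 and put on a log2 scale. The medians of the testis arrays then ran from 4.81 to 5.28, a gap over the limit of 0.1 set before the data were examined, so they were quantile normalized. A testis probe was kept if it was above its array's median on at least 3 arrays, which left 28816 probes. For testis, a noise limit was taken from the values below 0, mirrored around 0, as their percentile 99. It was 84.5 to 133.6 intensity units, and a testis group in which a probe was not above it on the arrays has no fold change here, or only a lower limit. Such a limit, written as at least a fold, sets the mean of the brighter group against the lowest signals above the noise limit. It carries no error of that mean, so it does not show that a gene differed. The brighter group may hold arrays that were not above the noise limit.

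All 12 arrays of a tissue went into a single limma fit, and each dose rate was compared with control by a two-sided moderated t test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold over all probes tested. Any difference among the groups was tested with the moderated F test, and a trend as a slope on the rank of the dose rate. The difference between tissues was tested as an interaction contrast on the value table, in a fit of all 24 arrays normalized within each tissue, over 23306 probes. The labels describe 12 mice but do not tie a kidney array to a testis array, so no covariate was used. The fit across tissues treats all 24 arrays as independent, which would not hold if both tissues came from the same mice. That would be so if the 12 mice gave all 24 arrays. Every error beside a log2 difference is the limma SE and every error beside a level is an SD, with n = 3.

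Fixed gene lists, chosen before the data were examined, were tested with limma camera with a preset correlation of 0.01 between genes, 1 probe per gene and at least 5 members. The adjustment ran over all lists and the 3 comparisons within a tissue. Camera with an estimated correlation and limma fry stand beside it. The lists held oxidative phosphorylation complex I, complexes II to IV, ATP synthase, the TCA cycle, fatty acid oxidation, cytosolic ribosomal proteins, p53 targets, DNA repair, the cell cycle, apoptosis regulators, antioxidant defence, heat shock and chaperones, immediate early genes, the interferon response, inflammation, matrix and fibrosis, kidney injury, testicular steroidogenesis, and markers of proximal tubule, macrophages, Sertoli cells, Leydig cells and round and elongated spermatids. Lists of other cell types and of the circadian clock, and in kidney also immediate early genes, inflammation and steroidogenesis, had fewer than 5 members measured and were not tested, 13 in kidney and 12 in testis.

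The genes named in the text follow a rule fixed before the data were examined. It takes up to 12 passing genes per direction and comparison, the 5 genes with the smallest p per direction where fewer than 5 passed, 4 members of each list that passed, 6 listed p53 targets where measured, and 10 probes of the F test and of the trend. Where the text names other genes, it says that they were chosen after their values were seen. A single item that the rule would also name is not reported here.

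The agreement between comparisons that share the same controls was set against 100 simulated draws of unchanged groups with shared controls. The pipeline was tested on simulated data with known changes. In kidney it called 76%, 94%, 98% and 100% of probes changed by log2 0.5, 1, 2 and 3 at the high dose rate, with 6 calls among 10703 unchanged probes. For testis the shares were 0%, 14%, 50% and 58%, with 2 calls among 28616 unchanged probes, so a change of log2 1 would mostly be missed there. Changes were added to values already normalized, and no array effects were simulated. These shares thus leave out the pull of dim kidney probes towards 0 and the influence of single arrays. They may be too high, and the false calls too few, for the real arrays. A raised complex I list was found in each tissue, and none of the other list tests (50 in kidney and 65 in testis) was called. The simulated noise was drawn independently for each probe, so genes of a list were not correlated there. In the kidney arrays the estimated correlation was 0.38 for the ribosomal list and 0.71 for the macrophage list. The simulation therefore cannot tell how often unchanged lists of correlated genes would be called.

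Alternatives fixed before the data were examined covered background correction, the kidney values as deposited with a floor of 16, a log2 scale and the testis filter but no background correction or quantile normalization, scaling to a common median, the floor, the filter, the replicate number as a block, the variance model (trend and robust), array weights, each array left out in turn, a fit of only both groups compared, and a threshold of unadjusted p under 0.05 with a 1.5-fold change. The slide of each array is not given in the sources used here, so a slide block could not be run. After the data were seen, 4 alternatives were added: the kidney noise from central scores, the kidney fit without both arrays that stood apart, and the testis noise limit as a filter, alone and with trend and robust. Both kidney arrays that stood apart, on the first principal component, were control replicate 2 (−22.1) and high replicate 2 (−16.5). Other ways of splitting the arrays were also tested.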

Results

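Mice lived for 485 days under γ-rays from a 137Cs source, 22 h per day, to ask which transcripts of kidney and testis differ after long irradiation at low dose rates. The low, mid and high dose rates were 0.032, 0.65 and 13 μGy/min and summed to 21, 420 and 8000 mGy. Kidney and testis were taken as soon as irradiation had stopped, and each tissue gave 3 arrays per group, including unirradiated controls. Kidney arrays detected 8879 to 10985 probes with a median of 39 to 44 beads per probe. Testis arrays had 12566 to 15806 probes above their noise limit. Within a group, arrays correlated at r = 0.978 to 0.995 in kidney, where arrays of different groups correlated at 0.976 to 0.993, and at 0.921 to 0.934 within groups in testis.

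Control probes on the kidney arrays differed between the groups. The signal of the low-stringency mismatch probes was 6.13% ± 0.61 of that of the matched probes in control, 5.64% ± 0.51 at low, 8.69% ± 0.19 at mid and 8.29% ± 0.82 at high dose rate (SD, n = 3 each). The control and low arrays lay between 5.10% and 6.82% and the mid and high arrays between 7.37% and 8.93%, so the ranges did not overlap. The difference of 2.61 percentage points had an exact permutation p = 0.00216, the smallest that 924 splits can give. Since this split was picked after the gap was seen, the p adds nothing to it. The high-stringency control signal also separated these arrays, at 61447.8 to 64383.2 in control and low against 54704.7 to 60545 in mid and high. Negative control signals overlapped slightly, at 171.2 to 205.4 against 147 to 172.6.

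At the low dose rate, the kidney lists of macrophage markers and cytosolic ribosomal proteins rose and the chaperone list fell with the preset correlation. Each had adjusted p = 0.506 with an estimated correlation. The macrophage list had a median log2 difference of +0.66, with all 7 of its 7 members higher. Among them, Lyz2, which encodes lysozyme, was at 8.22 ± 0.28 in control and 9.40 ± 0.57 at low dose rate, a log2 difference of +1.18 ± 0.34 (SE, n = 3, adjusted p = 0.453). C1qb and C1qa, subunits of complement C1q, differed by +0.79 ± 0.28 and +0.66 ± 0.24, and Cd74, the invariant chain of MHC class II, by +0.71 ± 0.22. Genes for cytosolic ribosomal proteins had a median of +0.15 and a mean of +0.13, with 50 of 57 higher, such as Rps9 (+0.40 ± 0.14, while its other probe gave −0.28), Rpl13a (+0.37 ± 0.12), Rps3 (+0.26 ± 0.10) and Rpl12 (+0.26 ± 0.18). Heat shock and chaperone genes had a median of −0.22, with 10 of 11 lower, such as Hspb1 (−0.64 ± 0.53), Hspa8 (−0.44 ± 0.10), Hsp90ab1 (−0.36 ± 0.13) and Xbp1 (−0.35 ± 0.14), a regulator of the unfolded protein response.

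The limma camera adjusted p was 1.25e-05 for the macrophage list, 6.15e-10 for the ribosomal list and 0.00881 for the chaperone list. The estimated correlation was 0.71 for the macrophage list. No member (0) passed over all probes in any of these lists, and adjusted over the list alone 5 macrophage genes and 1 chaperone gene passed. Averaged over its members, the macrophage list differed from the control mean by +1.01, +0.50 and +0.21 on the low arrays and by −0.10 to +0.07 on the control arrays. Without the first of these low arrays (replicate 2) its median was +0.34. That array also stood at +0.46 for kidney injury and −0.25 for the proximal tubule. At the low dose rate these lists had medians of +0.22 (5 of 5 higher, adjusted p = 0.103) and −0.15 (6 of 7 lower, adjusted p = 0.0885). The ribosomal median was +0.02 with median scaling. The chaperone call ended without control replicate 4 (adjusted p = 0.0677) and without low replicate 2 (adjusted p = 0.0603), in a range of 8.37e-04 to 0.506 over all alternatives. On the low arrays the mismatch control probes gave 5.64% ± 0.51 of the matched signal, against 6.13% ± 0.61 in control (SD, n = 3).

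Among single kidney probes at the low dose rate, none (0) of 10903 passed, with a smallest limma adjusted p of 0.141. At unadjusted p under 0.05 there were 909, and 12.3% of probes separated the groups without overlap, where 10% would by chance. Lowest in p among the lower probes was Hspa8, a constitutive cytosolic chaperone, at 13.95 ± 0.03 in control and 13.43 ± 0.12 at low dose rate (−0.52 ± 0.07, adjusted p = 0.175). This is its probe 3780402, while the chaperone list held its probe 2120315 (−0.44). Zbtb7a, a transcriptional repressor, differed by −0.67 ± 0.12, Ppp2r5e, a regulatory subunit of protein phosphatase 2A, by −0.46 ± 0.09, Dusp11 by −0.36 ± 0.07 and Rnf44 by −0.25 ± 0.05, each with adjusted p = 0.393. On the higher side, Mrps16, a mitochondrial ribosomal protein, differed by +0.48 ± 0.10, Ints6 of the Integrator complex by +0.44 ± 0.09, Ccdc12 by +0.38 ± 0.06 (adjusted p = 0.283), the spliceosomal Snrpd2 by +0.35 ± 0.08 (adjusted p = 0.43) and the arginine methyltransferase Prmt1 by +0.33 ± 0.06. The count was 5 from the deposited values with only a floor, a log2 scale and the testis filter (floored values below), 1 without both arrays that stood apart, 43 with array weights and 33 at unadjusted p under 0.05 with a 1.5-fold change.

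At the mid dose rate, the kidney genes Uqcrb and Ndufb9 rose, while the respiratory chain lists did not pass. Uqcrb, a subunit of complex III, rose from 8.57 ± 0.20 to 9.54 ± 0.02 (+0.97 ± 0.15, adjusted p = 0.0488), and Ndufb9, a subunit of complex I (probe 3780348), rose from 7.70 ± 0.10 to 8.23 ± 0.06 (+0.53 ± 0.09). Complex I had a median of +0.03 and a mean of +0.07, with 12 of 18 higher (camera adjusted p = 0.301). Complexes II to IV had a median of −0.01 and a mean of +0.06, with 9 of 17 lower (adjusted p = 0.502). A probe for the mitochondrially encoded complex I gene ND4L rose from 8.36 ± 0.36 to 9.35 ± 0.04, but was at 8.46 ± 0.15 at the high dose rate. The other, brighter ND4L probe (104480538) differed there, as it stayed higher at the high dose rate (+0.81, adjusted p = 0.0236). Isca1, which serves mitochondrial iron-sulfur cluster assembly, rose by 0.59 ± 0.10, and Rps4x, a small-subunit ribosomal protein, from 11.80 ± 0.12 to 12.25 ± 0.07. The organic anion transporter gene Slco3a1 fell from 9.83 ± 0.13 to 9.07 ± 0.10 (−0.75 ± 0.13), and Zbtb7a (probe 3780092) from 9.35 ± 0.17 to 8.65 ± 0.06 (−0.71 ± 0.12).

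Further genes that fell in kidney at the mid dose rate were Flywch1 (−0.61 ± 0.10), Rcor1, a corepressor of the REST complex (−0.56 ± 0.09), the focal adhesion gene Tns1 (−0.51 ± 0.07, adjusted p = 0.0425), the poly(A) polymerase gene Papola (−0.50 ± 0.08), Ints3 (−0.48 ± 0.08) and the elongation factor gene Eef1g (−0.28 ± 0.05). The adjusted p of the 13 named genes ran from 0.0425 to 0.0498, close to the threshold. In all, limma called 34 of 10903 probes, 20 up and 14 down, of which 13 had a symbol. At unadjusted p under 0.05 there were 1485, and 20.8% of probes separated the groups without overlap, where 10% would by chance. On these arrays the mismatch control probes gave 8.69% ± 0.19 of the matched signal, against 6.13% ± 0.61 in control (SD, n = 3). Each mid array also detected more probes (10183 to 10985) than each control array (8879 to 9846). The noise SD from central scores was lower on the mid arrays, at 20.9 to 22.3 against 24.3 to 26.8 in control.

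These mid counts moved with single arrays and settings, and the calls of named genes held in 3 (Eef1g) to 12 (Tns1) of 23 alternatives. The count was 1 without control replicate 3, 9 without control 4, 8 without low 3, 9 without low 4, 2 without mid 1, 1 without mid 3, 2 without mid 4, 2 without high 1, 103 without high 2 and 10 without high 3. It was 0 when only both groups compared were fitted, 2 with central noise, 6 without background correction, 10 from floored values, 6 with median scaling (2 up), 10 with no filter, 1594 with array weights, 90 without both arrays that stood apart and 120 at unadjusted p under 0.05 with a 1.5-fold change. With the replicate number as a block it was 14. Part of these were other probes. Those shared with the 34 calls were 1 from floored values, 3 without background correction, 7 with the block and 9 with no filter.

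Ribosomal protein genes at the mid dose rate had a median of +0.06 and a mean of +0.13 in kidney, with 40 of 57 higher, and this sign turned to −0.04 from floored values and −0.05 with median scaling. Rps4x was the member that passed over all probes (1), and 4 passed over the list alone. Rpl6 was higher by +0.92 ± 0.20 (adjusted p = 0.102), Rps3a1 by +0.70 ± 0.15 and Rps12 by +0.54 ± 0.19. The limma camera adjusted p was 2.26e-05, and adjusted p = 0.765 with an estimated correlation. It was 0.0719 without control replicate 4, and 0.531 and 0.391 under the scalings that turned the sign, in a range of 2.57e-10 to 0.765 over all alternatives. The mismatch control ratio of 8.69% on the mid arrays moved with this group too.

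At the high dose rate, the kidney lists of complex I and of complexes II to IV rose with the preset correlation. Each had adjusted p = 0.506 with an estimated correlation. Complex I had a median of +0.09 and a mean of +0.22, with 17 of 18 members higher. Among them, Ndufb9 rose from 7.70 ± 0.10 to 8.64 ± 0.12 (+0.94 ± 0.09, adjusted p = 0.00404) and Ndufa6 from 8.15 ± 0.28 to 9.13 ± 0.21 (+0.98 ± 0.16, adjusted p = 0.0354). Other complex I members that did not pass were Ndufb5 at +0.58 ± 0.15 (adjusted p = 0.137) and Ndufs3 at +0.27 ± 0.11. Complexes II to IV had a median of +0.08 and a mean of +0.17, with 14 of 17 higher. Uqcrb rose from 8.57 ± 0.20 to 9.63 ± 0.24 (+1.06 ± 0.15, adjusted p = 0.0214), while Cox6c was at +0.37 ± 0.14, the succinate dehydrogenase gene Sdhb at +0.36 ± 0.10 and Cox7a2l at +0.24 ± 0.10. COX2, here the mitochondrially encoded subunit 2 of cytochrome c oxidase and on no list, rose from 12.79 ± 0.13 to 13.46 ± 0.26 (+0.68 ± 0.12, adjusted p = 0.0492).

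The ribosomal list rose in kidney at the high dose rate with the preset correlation (limma camera adjusted p = 8.88e-09). With an estimated correlation it had adjusted p = 0.526. Its median was +0.11 and its mean +0.19, with 48 of 57 higher. Rps4x rose by 0.47 ± 0.07 (adjusted p = 0.025). In contrast, Rpl6 (+0.95 ± 0.20, adjusted p = 0.0729), Rpl21 (+0.86 ± 0.19) and Rps3a1 (+0.81 ± 0.15, adjusted p = 0.0541) did not pass. The elongation factor genes Eef1a1 and Eef1b2, which are on no list, rose by 0.70 ± 0.12 and 0.51 ± 0.09. Etfa, which passes electrons from fatty acid oxidation to the respiratory chain, rose by 0.52 ± 0.09, although its other probe gave +0.01 (adjusted p = 0.99), and the plasma carboxypeptidase gene Cpq rose by 0.50 ± 0.07.

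The limma camera adjusted p at the high dose rate was 1.86e-04 for complex I and 0.00174 for complexes II to IV. Over all probes 2, 1 and 2 members passed in complex I, complexes II to IV and the ribosomal list, and over the list alone 3, 2 and 8. Averaged over members, complex I was +0.29, +0.13 and +0.22 on the high arrays and −0.06 to +0.09 on the control arrays, and its median was +0.02 without high replicate 1 and +0.18 without high replicate 2. The ribosomal median was +0.05 without high replicate 1 and +0.07 with median scaling, which also took the median of complexes II to IV to +0.05. On the high arrays the mismatch control probes gave 8.29% ± 0.82 of the matched signal, against 6.13% ± 0.61 in control (SD, n = 3).

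**Figure D1:**
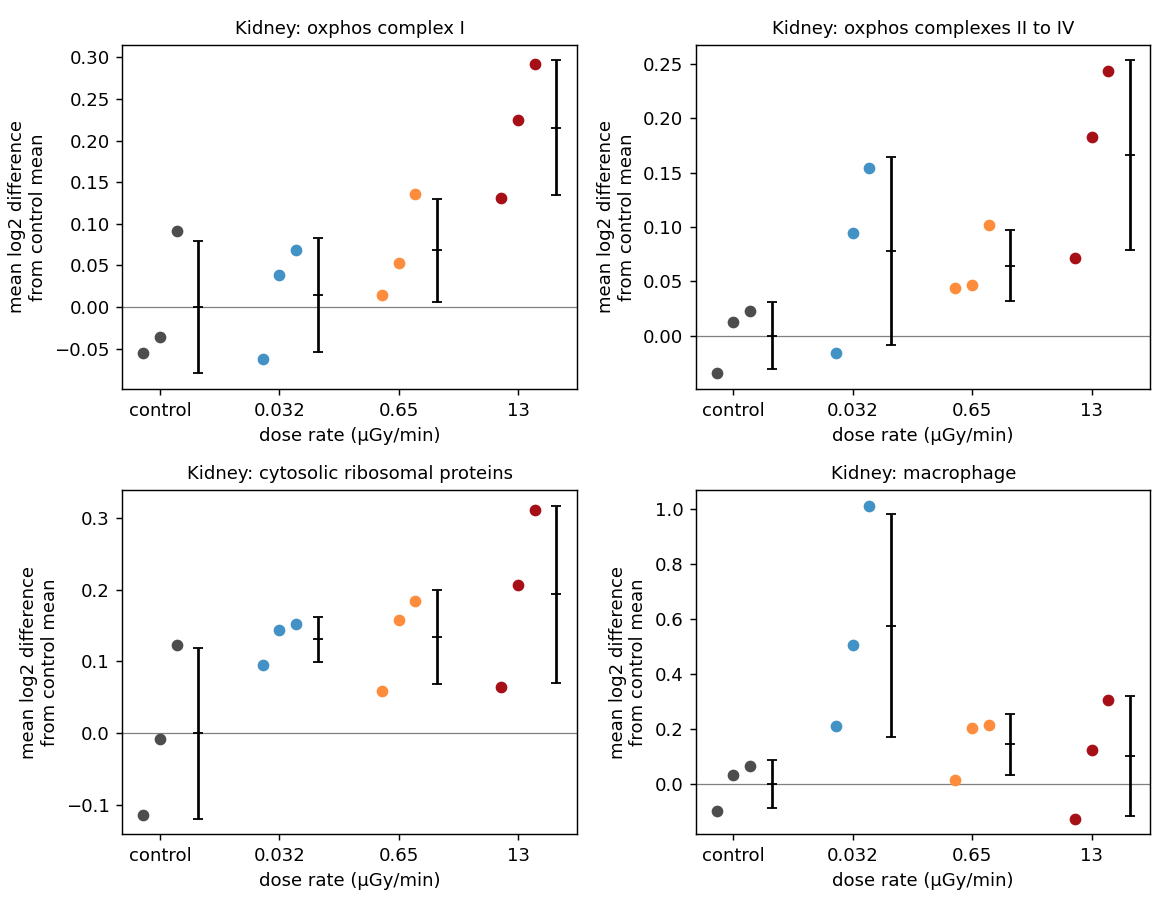
Gene lists in kidney by dose rate. Each point is an array and gives the mean over the list's members of the log2 difference from the control mean, for complex I, complexes II to IV, cytosolic ribosomal proteins and macrophage markers. Bars give the group mean and SD (n = 3).

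In kidney at the high dose rate, Zbtb7a fell from 9.35 ± 0.17 to 8.28 ± 0.16 (−1.08 ± 0.12, adjusted p = 0.01) and the Krüppel-like factor gene Klf3 from 10.36 ± 0.12 to 9.61 ± 0.20 (−0.75 ± 0.10, adjusted p = 0.0185). Rcor1 fell by 0.52 ± 0.09 (adjusted p = 0.0359). Kmt2e fell by 0.49 ± 0.07, and Brd3, a reader of acetylated histones, fell by 0.43 ± 0.06. Palld, an actin-binding cytoskeletal protein gene, fell by 0.77 ± 0.13 and Tns1 by 0.43 ± 0.07. The RNA-processing genes Papola and Rbm39 fell by 0.46 ± 0.08 and 0.42 ± 0.07, although the other Rbm39 probe gave +0.21 (adjusted p = 0.26). The liver-type phosphofructokinase gene Pfkl fell by 0.31 ± 0.06 (adjusted p = 0.0485). These falls were measured on the arrays with a mismatch control ratio of 8.29%.

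In all, limma called 55 of 10903 kidney probes at the high dose rate, 32 up and 23 down, of which 20 had a symbol. At unadjusted p under 0.05 there were 1299, and 13.8% of probes separated the groups without overlap, where 10% would by chance. Of the 23 alternatives, calls named here held in between 3 (Pfkl) and 21 (Ndufb9). Zbtb7a kept its call in 19, Klf3 in 18, Kmt2e in 17, Uqcrb and Brd3 in 14, Cpq in 12, and Rps4x and Palld in 11. Ndufa6, Eef1a1 and Rbm39 kept theirs in 9, Eef1b2 in 8, Etfa and Papola in 7, Rcor1 and Tns1 in 6 and COX2 in 4. The count was 200 without control replicate 2, 3 without control 3, 11 without control 4, 36 without low 3, 34 without mid 1, 23 without mid 3, 18 without mid 4, 89 without high 2 and 2 without high 3. It was 0 when only both groups compared were fitted and 0 from floored values, 29 without background correction, 16 with median scaling (5 up), 19 with no filter, 83 with trend and robust, 2063 with array weights, 158 without both arrays that stood apart and 105 at unadjusted p under 0.05 with a 1.5-fold change. With the replicate number as a block it was 27. Those shared with the 55 calls were 18 without background correction, 18 with no filter, 19 with the block and 45 with trend and robust.

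The mid and high dose rates called many of the same kidney genes, all with the same sign. Of 15 probes called at both, 8 were up and 7 down, and they included Uqcrb, Ndufb9, Rps4x, Zbtb7a, Rcor1, Papola and Tns1. Independent calls would share 0.0587 and 0.0295. Because the controls are shared the calls are not independent, and the number shared under unchanged groups was not simulated. Across all probes, the log2 differences of mid and high correlated at r = 0.59 (Spearman 0.56) with 70.4% of the same sign, low and mid at 0.41 (0.36) with 63.3%, and low and high at 0.36 (0.40) with 65.1%. Simulated unchanged groups with the same controls gave a mean r of 0.42 (central range −0.33 to 0.84), a Spearman of 0.38 and 64.0% of the same sign. The covariance was 0.0188 for mid and high, 0.0119 for low and mid and 0.00938 for low and high, against 0.00959 in the simulation. Part of the shared calls and of the correlation may come from the shared controls, which at 3 arrays cannot be split in parts of 2. Both groups also had a higher mismatch control ratio (8.69% and 8.29%) than control (6.13%).

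Compared with each other, the irradiated kidney groups differed most between the low dose rate and the others. Limma called 71 probes between mid and low, 49 up and 22 down, and 81 between high and low, 62 up and 19 down. Between high and mid it called 3, with 1 up and 2 down, while 924 had unadjusted p under 0.05. The mismatch control ratio was 5.64% ± 0.51 at low (SD, n = 3), against 8.69% at mid and 8.29% at high.

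Across all kidney groups, Ndufb9 was among the probes that differed most, with an F-test adjusted p of 0.0035. Its slope was +0.34 per step of dose rate (adjusted p = 0.0133). Cpq had a slope of +0.17 (adjusted p = 0.00901). Probe 102190086, which has no symbol, rose from 8.59 ± 0.04 in control to 9.58 ± 0.16 at high dose rate with a slope of +0.34 (adjusted p = 0.00437). Probe 104480538, whose target is the mitochondrial ND4L transcript, was higher by +1.39 at mid and +0.81 at high (F-test adjusted p = 0.00188). Probe 6650168 fell from 8.66 ± 0.04 to 7.85 ± 0.06 (F-test adjusted p = 0.00185, slope −0.24). Probe 4200112 fell by 0.95 ± 0.11 at the high dose rate (slope −0.30, adjusted p = 0.00901), and like 6650168 it has no symbol. The F test called 63 probes and the trend 94, 55 rising and 39 falling, while the mismatch control ratio went from 6.13% in control to 8.29% at high.

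The F count was 242 without control replicate 2, 13 without control 3, 22 without low 2, 13 without low 3, 22 without low 4, 13 without mid 1, 18 without mid 3, 6 without mid 4 and 3 without high 3. It was 14 without background correction, 26 from floored values, 23 with median scaling, 13 with no filter, 137 with trend and robust, 2119 with array weights and 236 without both arrays that stood apart. For the trend it was 316 without control 2, 13 without control 3, 58 without mid 3, 54 without mid 4, 44 without high 1, 161 without high 2 and 1 without high 3. The trend count was 4 from floored values, 17 with median scaling, 50 with no filter, 159 with trend and robust, 467 with array weights and 228 without both arrays that stood apart. With the replicate number as a block, the F count was 18 and the trend count 13, and most of these trend calls fell.

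Genes that answer acute DNA damage through p53 did not pass in kidney at any dose rate. Cdkn1a, which encodes the cell cycle inhibitor p21, differed by +0.08 ± 0.08 at low, −0.05 ± 0.08 at mid and +0.16 ± 0.08 at high (adjusted p = 0.86, 0.841 and 0.516). Ccng1 differed by −0.03 ± 0.17, +0.07 ± 0.17 and +0.15 ± 0.17 (adjusted p = 0.981, 0.902 and 0.819). The 5 measured p53 targets had medians of −0.03, +0.02 and +0.16, with 1, 3 and 5 of 5 higher and camera adjusted p of 0.984, 0.808 and 0.0659, and at the high dose rate adjusted p = 0.506 with an estimated correlation. The DNA repair list had medians of −0.04, −0.03 and +0.03 and the cell cycle list of 0.00, −0.05 and −0.02, with camera adjusted p of 0.703 or more. Only 12 of 62 listed DNA repair genes, 8 of 52 cell cycle genes and 5 of 34 p53 targets were tested. These values say nothing about the others.

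Of 51 kidney list tests 7 passed, and lists that passed at no dose rate are given here at the dose rate closest to passing, with complexes II to IV at low beside them. The proximal tubule and kidney injury lists, closest at low, are given above. At the low dose rate the interferon response list was at +0.11 (6 of 6 higher, camera adjusted p = 0.0681), complexes II to IV at +0.06 (adjusted p = 0.0658) and the TCA cycle at −0.05 (6 of 7 lower, adjusted p = 0.103). On the same arrays fatty acid oxidation was at −0.10 (7 of 8 lower, adjusted p = 0.502). At the high dose rate matrix and fibrosis was at −0.16 (6 of 6 lower, adjusted p = 0.0808), ATP synthase at +0.06 (adjusted p = 0.178), antioxidant defence at +0.06 (adjusted p = 0.333) and apoptosis regulators at −0.04 (8 of 10 lower, adjusted p = 0.517). With limma fry none (0) of the 51 passed, and its lowest adjusted p was 0.247.

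In testis at the low dose rate, Eml3, a microtubule-associated protein gene, was called at 4.00 ± 0.00 in control and 6.02 ± 0.15 irradiated (adjusted p = 0.0412), but neither group was above the noise limit, so no fold change is given. By group means, Atp5md, a small ATP synthase subunit gene, was at least 1.40-fold lower (adjusted p = 0.088) and Rp1 at least 1.30-fold lower (adjusted p = 0.344). Olfr924 was at least 1.10-fold lower (adjusted p = 0.174) and Krt8, an epithelial keratin gene, at least 1.02-fold lower (adjusted p = 0.186). Only the control group was above the noise limit for these genes, and they did not pass. Moap1, Pfkp, Wdr44, Raver1 and Chrna4 were not above it in either group (adjusted p from 0.165 to 0.43). Limma called 7 of 28816 probes, 6 up and 1 down, with 1257 at unadjusted p under 0.05, and 8.86% of probes separated the groups, where 10% would by chance. With the arrays of a testis group numbered 1 to 3 in the order of their labels, the count was 0 without control 1, control 2 or low 2, 3 without control 3, 1 without low 1 and 4 without low 3. It was 14 without mid 3 and 11 without high 3. It was 3 as deposited, 1 with median scaling, 3 with the floor at 50, 3 with no filter, 0 with trend and robust, 0 above the median on all arrays, 0 with the noise limit, 0 when only both groups compared were fitted and 1142 at unadjusted p under 0.05 with a 1.5-fold change. Those shared with the 7 calls were 3 as deposited, 2 with no filter and 0 with the floor at 50.

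At the mid dose rate in testis, Cblb, a ubiquitin ligase gene, was at least 1.07-fold higher by group means (adjusted p = 0.0314). It was not above the noise limit on all arrays of either group. Ankrd17 was called with control not above the noise limit, and the glutamate receptor gene Gria3, Gtf3c6 and the apoptosis modulator gene Moap1 were called with neither group above it, so they have no fold change (adjusted p from 0.0295 to 0.0426). Limma called 18 probes, 16 up and 2 down, with 2239 at unadjusted p under 0.05, and 14.5% of probes separated the groups, where 10% would by chance. This count was 5 without control 1, 6 without control 2, 5 without control 3, 0 without mid 1, 4 without mid 2, 0 without mid 3 and 10 without high 3. It was 11 as deposited, 32 with the floor at 50, 44 with no filter, 11 above the median on all arrays, 214 with trend and robust, 31 with array weights, 16 (6 up, and 3 of them among the 18) when only both groups compared were fitted, 0 with the noise limit, 202 with the noise limit, trend and robust, and 1721 at unadjusted p under 0.05 with a 1.5-fold change. All 18 were called with no filter and with array weights, and 10 as deposited. Only 1 of the 18 was called with the floor at 50, and 0 above the median on all arrays. With trend and robust 0 of the 18 were called, with or without the noise limit.

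At the high dose rate in testis, the higher genes with the smallest p that were above the noise limit in both groups were ND1, COX2 and Fam3c, of which ND1 and COX2 are mitochondrially encoded. The complex I gene ND1 was at 13.35 ± 0.03 in control and 14.12 ± 0.05 at high dose rate (+0.77 ± 0.11, adjusted p = 0.101), COX2 was at +0.62 ± 0.13 (adjusted p = 0.277) and the secreted-factor gene Fam3c at +0.69 ± 0.14 (adjusted p = 0.281). The other probe gave +0.22 for ND1 (adjusted p = 0.632) and +0.50 for COX2 (adjusted p = 0.312). By group means and without passing, Gpn3 was at least 1.65-fold lower (adjusted p = 0.224). Tnfrsf10b, a death receptor gene and p53 target, was at least 1.10-fold lower (adjusted p = 0.0546, and under 0.05 in 7 of 21 alternatives), while its other probes gave −0.04 and +1.36. The neuronal enolase gene Eno2 was at least 1.02-fold higher (adjusted p = 0.224), and Sprr2d, Chrna4, Cfap97d2 and Bach2 have no fold change (adjusted p from 0.118 to 0.224). Limma called 5 probes, 4 up and 1 down, with 2776 at unadjusted p under 0.05, and 16% of probes separated the groups, where 10% would by chance.

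On the first principal component high 2 and high 3 stood apart from the other testis arrays, at 67.1 and 95.5, where all others were at 6.41 or lower. They had the fewest probes above the noise limit (12891 and 12566). The high count in testis was 0 without control 2, control 3 or high 3, 1 without high 2, 9 without low 1, 16 without low 2, 9 without mid 1 and 18 without mid 3. It was 35 with the floor at 50, 11 with no filter, 1 above the median on all arrays, 0 when only both groups compared were fitted, 338 with trend and robust, 2 with the noise limit, 385 with the noise limit, trend and robust, and 1876 at unadjusted p under 0.05 with a 1.5-fold change. All 5 high calls were also called with no filter. None (0) of the 5 was called with the floor at 50, above the median on all arrays, with trend and robust, or with the noise limit. Of the 30 calls at the 3 dose rates, 26 (86.7%) were not above the noise limit on any of the 6 arrays compared, and none (0) was above it on all arrays of a group.

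Across all testis groups the F test called 35 probes. Among them was A530095I07Rik, at the floor in control (4.00 ± 0.00) and at 5.66 ± 0.21 at high dose rate (adjusted p = 0.00398). The limma trend called 0, with a smallest adjusted p of 0.178. The F count in testis was 23 without control 3, 14 without low 1, 22 without low 3, 17 without mid 1, 11 without mid 2, 23 without mid 3, 22 without high 1 and 12 without high 3. It was 74 with no filter, 616 with trend and robust, 490 with the noise limit, trend and robust, 0 with the noise limit and 0 above the median on all arrays. The trend count was 467 with trend and robust, 426 with the noise limit, trend and robust, 2 above the median on all arrays and 1 with the floor at 50, with no filter or with the noise limit. Between irradiated testis groups, 22 probes were called between mid and low, 7 between high and low and 28 between high and mid. The log2 differences of low and mid, low and high, and mid and high correlated at r = 0.47, 0.44 and 0.49 (covariance 0.153, 0.144 and 0.172), against 0.50 (central range 0.12 to 0.87, covariance 0.166) in simulated unchanged groups with the same controls, and mid and high shared 1 call.

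In testis, Cdkn1a, Ccng1 and the spermatid lists showed no difference that passed. Lists of earlier germ cells had 2 members (spermatogonia) and 1 (spermatocytes) and were not tested. Cdkn1a differed by +0.11 ± 0.26 at low, −0.24 ± 0.26 at mid and +0.10 ± 0.26 at high (adjusted p = 1, 0.9 and 0.943). By group means, Ccng1 was at least 1.17-fold lower at low (adjusted p = 1). It was at −0.55 ± 0.43 at mid (adjusted p = 0.84), with no fold change at high. The round spermatid list had medians of −0.03, 0.00 and +0.01 (mean −0.02) at low, mid and high and the elongated spermatid list of 0.00, −0.07 and −0.03, with 5 members each and camera adjusted p of 0.799 or more. Leydig cell markers had medians of −0.30 (6 of 6 lower, adjusted p = 0.282), −0.26 and +0.25. Sertoli cell markers had medians of −0.08 (mean +0.13), +0.12 and +0.19 (adjusted p = 0.282 at high), and testicular steroidogenesis of −0.14, −0.01 and +0.20 (adjusted p = 0.282 at high).

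None (0) of 66 testis list tests passed with limma camera, and the lowest adjusted p was 0.249, for antioxidant defence at the high dose rate (median +0.12, 12 of 16 higher). Ribosomal protein genes had medians of 0.00, +0.01 and 0.00 at low, mid and high, complex I of 0.00, −0.03 (mean +0.15) and +0.06, complexes II to IV of −0.04, −0.09 and +0.10, and ATP synthase of −0.05 (mean −0.40, adjusted p = 0.282), −0.05 and +0.05. Immediate early genes were at −0.36 at mid (adjusted p = 0.282), apoptosis regulators at −0.14 at low (adjusted p = 0.282), inflammation at +0.36 at high (mean +0.01, adjusted p = 0.911), macrophages at +0.25 at low (adjusted p = 0.509) and p53 targets at −0.17 at mid (mean +0.01, adjusted p = 0.989). DNA repair, the cell cycle, heat shock, the interferon response, matrix and fibrosis, the TCA cycle and fatty acid oxidation had adjusted p of 0.636 or more. In testis 20 of 62 listed DNA repair genes, 18 of 52 cell cycle genes and 8 of 34 p53 targets were tested. The count of passing lists was 2 with median scaling and 1 without high 3.

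Few probes were called for a different change in kidney and testis, and those lay at background in kidney. The interaction contrast called 0 of 23306 probes at low (1227 at unadjusted p under 0.05), 3 at mid and 5 at high. Cdca7l, named for its association with cell division, and Sprr2d were called at the high dose rate (adjusted p = 0.0457 for each difference). Each probe called was detected on 0 of the 6 kidney arrays compared, and Sprr2d was above the noise limit on 0 testis arrays, so no fold change is given. Of the 34 kidney probes called at mid, 27 were above background in testis and 20 had the same sign there, and of the 55 called at high 45 were above background and 34 had the same sign. Over all 7662 probes above background in both tissues, 56.2% at mid and 51.9% at high had the same sign. With the noise limit, trend and robust, 2 (mid) and 6 (high) of the kidney calls were also called in testis with the same sign. Mid and high arrays stood apart from control and low arrays in both tissues, so array sets could also give this agreement. With no filter the interaction counts were 18, 90 and 74, and over left-out arrays they ran from 0 to 5, 1 to 11 and 0 to 41.

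**Figure D2:**
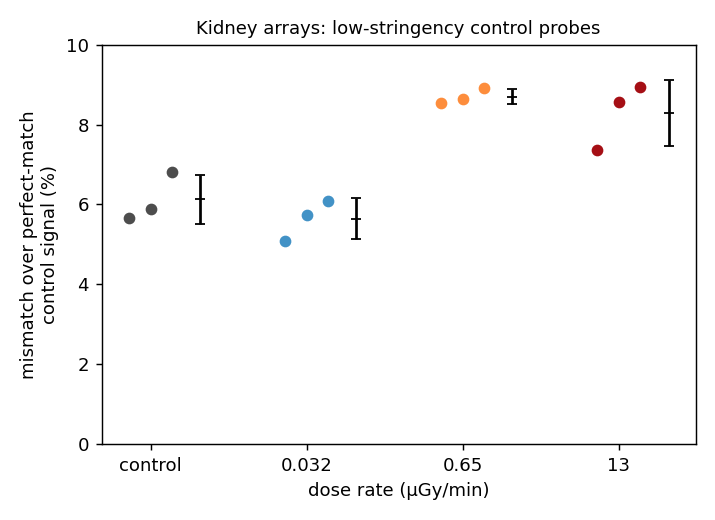
Low-stringency control probes of the kidney arrays by dose rate. Each point is an array and gives the signal of the mismatch probes as a percentage of that of the matched probes. Bars give the group mean and SD (n = 3).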

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

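In this part, the test of testis calls against the noise limit and the reading of probe pairs within a tissue were chosen after the result was seen, and all other tests were chosen before their values were computed.

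Some probes and lists were called for a different change in kidney and testis. These were 3 probes at the mid dose rate and 5 at the high dose rate, counts that 35 and 21 of 100 splits reached. Each of them was detected on 0 of the 6 kidney arrays compared. Cdca7l, at +1.61 (kidney minus testis), and Sprr2d, at −2.07 (each at the high dose rate and with adjusted p = 0.0457), are thus values at background that give no fold change. The ribosomal list differed by +0.157 at the low dose rate (limma camera adjusted p = 2.32e-04, and adjusted p = 0.794 with an estimated correlation) and by +0.0809 at the high dose rate (adjusted p = 0.0131, and adjusted p = 0.794 with an estimated correlation). The chaperone list differed by −0.295 at the low dose rate (adjusted p = 0.0495, and adjusted p = 0.794 with an estimated correlation). In kidney the mismatch control probes gave 8.69% of the matched signal at mid and 8.29% at high dose rate, against 6.13% in control.

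The mid and high arrays separated from the control and low arrays in both tissues, along the second principal component of each. The effect of this split correlated between the tissues at r = 0.25 over 7662 probes, where the highest of the other splits gave 0.173. This split was picked because these arrays showed it, while the others were drawn at random. The ranking therefore does not measure how unusual the correlation was. In 167 genes with more than 1 probe the correlation between tissues was 0.347 for the same probe and 0.0227 through the other probe of the gene, a ratio of 0.0654 (95% interval −0.264 to 0.346), as could arise if arrays were handled as separate sets. This test, which was to tell such sets from a dose-rate response of whole genes, cannot do so, because even within a tissue the other probe gave only 0.156 (kidney) and 0.0989 (testis), against 0.781 for the difference between tissues. Hybridisation stringency could contribute as well, since the within-group slope on the mismatch ratio correlated with the split at r = 0.154, a value reached in a share of 0.0324 of 1296 rearrangements. Responses of whole genes or of single transcript forms in both tissues stay open, as dose rate and array set cannot be told apart in this design and neither the slides nor whether both tissues came from the same mice is given in the sources used here.

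The testis calls at single dose rates lay near the floor. A small spread of values at the floor could account for them, since 86.7% of the calls were not above the noise limit on any of the 6 arrays compared. Whether any of the rest follow the dose rate stays open.

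Other splits of the arrays tested whether chance may account for the counts. Among 10 splits of 6 arrays, which are too few for a share under 0.05, as many probes as in the real split were called by 10 for kidney low (real 0, highest other 0), 1 for kidney mid (34, highest other 0), 1 for kidney high (55, highest other 1), 6 for testis low (7, highest other 13), 1 for testis mid (18, highest other 14) and 8 for testis high (5, highest other 15). Among 100 splits of 12 arrays, chance is argued against for the kidney F test (1 split, real 63, highest other 26) and the kidney trend (1 split, real 94, highest other 42). For the testis F test the share was also under 0.05, but another split called as many (2 splits, real 35, highest other 35). That testis count was 0 with the noise limit and 0 above the median on all arrays, so it gives no support for probes above the noise limit. The splits took no account of the replicate number or of array sets. Chance could give the kidney list calls (29 splits, real 7, highest other 14), the testis trend (100 splits, real 0, highest other 2) and the testis list calls (100 splits, real 0, highest other 8). It could also give the differences between tissues at low (100 splits, real 0, highest other 10), mid (35 splits, real 3, highest other 11) and high (21 splits, real 5, highest other 22).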

How the results depend on the processing

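In this part, the kidney noise from central scores, the kidney fit without both arrays apart on the first component, and both uses of the testis noise limit were chosen after the result was seen, and the cause of each shift was not tested. Kidney counts at low, mid and high, of the F test and of the trend were 0, 34, 55, 63 and 94. They moved to 6 (mid), 29 (high) and 14 (F) with no background correction, and to 5, 10, 0, 26 and 4 from deposited values with only a floor, a log2 scale and the testis filter (floored values). Median scaling gave 6 (2 up), 16 (5 up), 23 (F) and 17 (11 up), so that most calls at mid and at high pointed down, and all of the 6 and 16 were shared with the calls given above. No filter gave 10, 19, 13 and 50 (mid to trend), trend and robust gave 83, 137 and 159 (115 up, from high to trend), and array weights gave 43, 1594, 2063, 2119 and 467 (311 up). Central noise gave 2 at mid. Leaving out both arrays apart on the first component gave 1, 90, 158, 236 and 228 (165 up). Fitting only both groups compared gave 0 at mid and 0 at high, and unadjusted p under 0.05 with a 1.5-fold change gave 33, 120 and 105. List calls in kidney fell from 7 to 0 with an estimated correlation and to 0 with fry. The ribosomal list at mid reversed to −0.0359 (floored values) and −0.0544 (median scaling).

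With the replicate number as a block, kidney counts were 14 (mid), 27 (high), 18 (F) and 13 (trend, 5 up), and 7 lists passed. The 13 pairs of arrays with the same number had r from −0.17 to 0.47, median 0.19, with 10 over 0.1 (among them all 7 that include a control array, 0.126 to 0.466), and 7 of 12 arrays correlated best with their own number. Pairs with other numbers had a median of −0.05, with 11 of 41 over 0.1. The labels do not say what the number stands for, so the numbers were not used as a pairing.

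Testis counts at low, mid and high, of F and of the trend were 7, 18, 5, 35 and 0. They moved to 3 and 11 (low and mid) as deposited, 1 at low with median scaling (and 2 lists), 3, 32, 35 and 1 (low, mid, high and trend) with the floor at 50, and 3, 44, 11, 74 and 1 with no filter. Above the median on all arrays gave 0, 11, 1, 0 and 2, trend and robust gave 0, 214, 338, 616 and 467, and array weights gave 31 at mid. The noise limit gave 0, 0, 2, 0 and 1, and with trend and robust it gave 0, 202, 385, 490 and 426. None (0) of the 18 calls at mid and 5 at high was called with trend and robust, with or without the noise limit. Only both groups compared gave 0 at low, 16 at mid (6 up, 3 shared with the 18) and 0 at high, and unadjusted p with a fold change gave 1142, 1721 and 1876. The difference between tissues had 18, 90 and 74 calls with no filter.

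Over left-out arrays, kidney counts ran from 0 to 0 at low, 1 to 103 at mid, 2 to 200 at high, 3 to 242 for F, 1 to 316 for the trend and 5 to 10 for lists. Testis counts ran from 0 to 14, 0 to 22, 0 to 18, 11 to 32 and 0 to 0, with 0 to 1 lists, and differences between tissues from 0 to 5, 1 to 11 and 0 to 41. The correlation between dose rates ran from 0.33 to 0.58 (low and mid), 0.21 to 0.51 (low and high) and 0.44 to 0.69 (mid and high) in kidney, and from 0.41 to 0.57, 0.38 to 0.55 and 0.41 to 0.58 in testis. Of the values of single genes and lists over all alternatives, 1840 kept their side of the threshold, 545 no longer passed, 67 passed that had not and 2 reversed. The 1840 include values that passed in neither fit, while all 545 came from genes and lists that had passed. Calls of named kidney genes held in 3 to 12 of 23 alternatives at mid and in 3 to 21 at high. Of the 1840, 20 changed sign, and these passed in neither fit.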

Other observations

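In this part, the genes and the mitochondrial list were chosen after their values were seen, as were the tests of array sets and of a joint nuclear rise, while the test of bright probes was chosen before.

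Some single kidney genes, picked after their values were seen, were higher at the low dose rate and did not pass. Both probes of H2-Ab1, an MHC class II chain gene, gave +0.52 ± 0.15 and +0.68 ± 0.25 (SE, n = 3, adjusted p = 0.454 and 0.512). H2-DMb2, H2-DMb1 and H2-DMa, which load peptides onto class II, gave +0.59 ± 0.21, +0.41 ± 0.12 and +0.23 ± 0.07, and the interferon-induced chemokine gene Cxcl9 gave +0.35 ± 0.13. Between high and low dose rate, the H2-Ab1 probe with the smaller p fell by 0.82 ± 0.15 (adjusted p = 0.0406). The immunoglobulin genes Ighm and Igkc gave +1.28 ± 0.76 and +0.62 ± 0.56 at low, +1.90 ± 0.76 and +0.83 ± 0.56 at mid and −0.32 ± 0.76 and −0.37 ± 0.56 at high. Among p53-responsive genes, Gdf15, a stress cytokine gene, gave +0.59 ± 0.19 at high (adjusted p = 0.233) and Zmat3 gave +0.17 ± 0.09.

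In testis, the fit with the noise limit, trend and robust called 202 of 16325 probes at the mid dose rate and 385 at the high dose rate, and 0 at low, where the noise limit alone called 0 at mid and 2 at high. The same fit called 138 probes between mid and low, 408 between high and low and 26 between high and mid. Most calls thus lay between the mid and high arrays and the control and low arrays. For that split, dose rate and array set cannot be told apart, which holds for every gene given below. The mid count was 75 without control 1, 110 without control 2, 97 without mid 1 and 126 without mid 2. The high count was 83, 47 and 114 without control 1, 2 and 3, 708 without high 1, and 167 and 173 without high 2 and high 3, which stood apart on the first component. Every gene given here as higher or lower passed in that fit at adjusted p under 0.05. Probes of some mitochondrially encoded genes rose there: ND1 by 0.60 ± 0.06 at mid and 0.77 ± 0.06 at high, ATP6 by 0.59 ± 0.07 and 0.57 ± 0.07, and COX2 by 0.67 ± 0.08 and 0.62 ± 0.08. Other probes of these genes gave less in the main fit. At mid and high they gave +0.05 and +0.22 for ND1, +0.11 and +0.24 for ATP6, and +0.44 and +0.50 for COX2. A probe for ND4 gave −0.01 at mid. Single nuclear genes that rose at mid were Ndufa6 (+0.78 ± 0.15, adjusted p = 0.00631), Uqcrb (+0.66 ± 0.14, adjusted p = 0.0114), Ndufb5 (+0.64 ± 0.13) and Cox6c (+0.40 ± 0.08), as did Rpl6 (+0.94 ± 0.18) and Rps9 (+0.72 ± 0.13). The fixed lists did not pass in testis at mid, with medians of −0.03 for complex I and −0.09 for complexes II to IV (camera adjusted p = 0.799 each) and +0.01 for ribosomal proteins (34 of 61 higher, adjusted p = 0.636). Fasn, the fatty acid synthase gene, rose by 0.68 ± 0.11 at mid and 0.66 ± 0.11 at high, and the retinaldehyde dehydrogenase gene Aldh1a1 rose by 0.89 ± 0.18 at high. The glycolytic gene Eno1 fell by 0.36 ± 0.09 at mid and 0.39 ± 0.09 at high, and the antiproliferative gene Btg1 fell by 0.36 ± 0.08 at mid. Of sperm genes, Odf2 rose by 0.56 ± 0.12 at mid and Akap3 fell by 0.31 ± 0.08 at high. Over the 12 fits that each leave out 1 array, the calls of ND1, ATP6, COX2 and Fasn held in 12 at mid and at high, and that of Rps9 in 12 at mid. The others held in 4 (Eno1) to 11 (Ndufa6) at mid, and in 6 (Aldh1a1), 7 (Akap3) and 8 (Eno1) at high.

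Probes for transcripts of the mitochondrial genome had higher signal at mid and high dose rate in both tissues, with array medians of +0.31 ± 0.06 at mid and +0.13 ± 0.05 at high in kidney (20 probes) and +0.24 ± 0.11 and +0.47 ± 0.09 in testis (17 probes, SD, n = 3). A general shift of bright probes is argued against, since lists matched for brightness had a typical median of −0.007 in kidney and −0.016 in testis at the high dose rate. At most 12 of 10000 such lists had as high a median. They drew unrelated probes, while mitochondrial probes were correlated (0.20 in kidney and 0.47 in testis). That count therefore does not measure how unusual the rise was. Array sets and a joint rise of nuclear respiratory genes could each play a part that these tables do not settle, with medians for high minus mid of −0.0529 in kidney and +0.136 in testis (14 of 17 higher), +0.113 for low minus control in testis (14 of 17 higher), and a highest testis median of +0.101 for the nuclear lists. That highest value is from the high dose rate, while at mid 10 of 18 complex I members and 13 of 17 of complexes II to IV were lower in testis. Camera with an estimated correlation gave unadjusted p of 0.00828 and 0.0333 at mid and high in kidney and of 0.0694 and 0.0205 in testis. Probes of the same gene did not always move together, as with ND5 in kidney at mid (−0.24 and +0.46) and ND1 in testis at mid (+0.60 and +0.05). A rise of mitochondrial transcripts thus stays a hypothesis to be tested by another method.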
